A study of Mus musculus with 4 samples.

How the data were processed

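Polyadenylated RNA of 4 cultures of mouse embryonic fibroblasts from female E13.5 fetuses was sequenced with a stranded mRNA kit, per the labels' protocols. The fibroblasts came from B6 mothers that carried the Xist-deltaA mutation and from B6-JF1 F1 fathers, per the labels. An X chromosome with Xist-deltaA cannot be silenced, so the paternal JF1 X is the inactive one in these females, and reads with JF1 variants report on it. The comparison was between 2 libraries with wild-type Smchd1 (WT) and 2 libraries with the MD1 allele on both copies of Smchd1 (MD1).

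One table of 22691 genes was used. It held 4 kinds of values. Allele-specific reads per X-linked gene and library were deposited as counts and were whole numbers for each X-linked gene of the table. The share of these reads from JF1 was deposited as a fraction, and was given where a gene had 10 or more such reads in a library, while the highest read number without a share was 9. Share times reads came out whole, within 0.001, for 100% of values, so JF1 counts were recovered by multiplication. The authors also deposited the summed reads and the read-weighted JF1 fraction of each group. Total expression was deposited as FPKM, with 1 mean per group made by the authors and no value per library. The submitters' processing notes name the genome build mm9, Cufflinks 2.2.1 and Cuffdiff, with no role or order. The aligner, the source of the JF1 variants and the annotation are not given in the sources used here. Reads that map better to the B6-based reference than to JF1 sequence would lower a JF1 share in both groups. The labels give no batch or date.

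Gene starts in the table were counted from 0. With the start moved up by 1, the spans of 9510 genes equalled the RefSeq gene length in GRCm38, against 620 with the start as given, and 21376 genes could be matched by symbol. Coordinates are printed 1-based in mm9, and no coordinates of another build were used.

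An X-linked gene other than Xist was informative when a share was given in all 4 libraries and its allele-specific reads averaged 20 or more per library, which held for 391 genes. Paternal share means the JF1 percentage of allele-specific reads. The share per library was the mean over informative genes, compared with an exact two-sided permutation test, for which 2 libraries against 2 cannot give a p under 0.333. Single genes were tested with edgeR 4.0.16 (R 4.3.3), by the quasi-likelihood F-test on JF1 and B6 counts with a term for each library, an allele term and an allele-by-genotype term, two-sided. Library sizes were set to the allele-specific total for both alleles, and p-values were adjusted by Benjamini-Hochberg over the 391 genes at an FDR of 0.05. No label says whether replicates came from separate fetuses, so p-values measure the spread between these samples, which may be technical. The reads of the 2 replicates differed far beyond sampling noise in each group. The chi-square per degree of freedom was 98.1 in WT and 90.6 in MD1, so the replicates were not counted as repeat sequencing of the same library. Separate libraries of the same culture could differ in this way too, so these values do not show that the replicates are independent. Paternal expression was called at a mean share of 10% or more. The test of position compared the mean absolute difference in rise between neighbouring genes with 100000 random orders of the same genes, one-sided.

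In data simulated for MD1 against WT on the read numbers of the 391 genes, the edgeR test called 47.2%, 77.6%, 92.8% and 99.2% of genes whose share was raised by 2, 5, 10 and 30 points, and 2.10% of its calls were false. These rates rest on 5 draws and on a simulated spread between libraries. That spread was set alike for all genes and was not estimated from these data. Each simulated gene started from a share above 0, while 173 real genes had no JF1 read in WT. The percentage of false calls also depends on the 191 genes left unchanged in each draw. The real rates may therefore differ.

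The test planned for total expression was limma on values per library. With 1 FPKM mean per group it could not be fitted, and neither could the planned camera and fry tests of gene lists. Ratios are therefore described without p-values, as log2 of (FPKM + 1) in MD1 over WT, for genes with a mean FPKM of 1 or more and above 0 in both groups. This scale understates the change of low genes. For a gene list with at least 5 measured genes, the median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 10 bins. A percentile outside 2.5 to 97.5 was taken as standing apart, which describes these libraries only. The planned JF1 share of autosomal genes was not computed, since allele-specific values in the table cover the X chromosome.

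The planned tests, the 21 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took Smchd1 and Xist, each measured gene of the X escape list, the 12 X genes with the largest rise and the 6 with the largest fall in paternal share among genes past the FDR whose libraries did not overlap, and the 6 deepest X genes that stayed under 5% in all 4 libraries. Only 1 fall passed, so falls without overlap were added and named as not passing. Values of some genes that the rule took are not reported here. For total expression the rule asked for p-values, and the 12 largest and 12 smallest log2 ratios were named in their place, with the 4 largest ratios in size of each list as candidates for examples. The lists covered X escape genes, clustered protocadherins, imprinted genes near Snrpn and Igf2r, other imprinted genes, Hox genes, X-linked germline families, fibroblast, epithelial, endothelial, blood and immune, erythroid, neural, skeletal muscle, smooth muscle and cartilage or bone markers, proliferation, p53 and senescence, interferon, extracellular matrix, stress and silencing factors.

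Alternatives included pooled reads, the median, other read minimums, limma 3.58.1 on the share, Fisher's exact test on summed reads, a prior count of 2, a replicate block, each library left out (with the lone library of a group assumed to vary like the other genotype), other bounds, another pseudocount of 0.1, other FPKM filters and other scalings. Figures were drawn with matplotlib 3.10.9, and other computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

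Allele-specific reads on X totalled 544330 and 521768 in the WT libraries and 704635 and 806626 in the MD1 libraries. The median informative gene had 394 and 449 reads in WT and 500 and 653 in MD1. The most abundant gene took 18.3% of reads (Bgn, WT replicate 1), and Flna took 12.1%, 17.5% and 14.4% of the reads of WT replicate 2, MD1 replicate 1 and MD1 replicate 2. Intervals and limits cover counting error only, since reads are not independent molecules.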

Results

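Embryonic fibroblasts of female E13.5 mouse fetuses were profiled by RNA-seq to ask how the loss of SmcHD1, a chromatin protein related to the SMC family that is enriched on the inactive X, affects silencing of that chromosome. There were 4 libraries, 2 from fibroblasts with wild-type Smchd1 (WT) and 2 from fibroblasts homozygous for the MD1 allele (MD1). All carried Xist-deltaA on the maternal B6 X, so the paternal X, of JF1 origin, was the inactive one. Allele-specific reads of X-linked genes totalled 521768 to 806626 per library.

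Smchd1 (chromosome 17, 71693834 to 71824683, mm9) had a mean FPKM of 14.7 in WT and 1.94 in MD1, or 13.1% of the WT level. Xist (X, 100655712 to 100678572), the RNA that coats the inactive X, had 22.04 FPKM in WT and 26.9 in MD1. Its reads came from the paternal allele at 99.9% ± 0.0123 (SD, n = 2) in WT and 99.9% ± 0.0181 (SD, n = 2) in MD1, with 9226 to 19371 allele-specific reads per library. The FPKM values are the authors' group means and have no spread.

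The paternal X contributed little to X-linked RNA in WT and a large part of it in MD1. Over 391 informative genes the mean paternal share was 0.691% ± 0.0449 (SD, n = 2) in WT and 17.9% ± 0.352 (SD, n = 2) in MD1, a difference of 17.2 points. Single libraries had 0.723% and 0.659% in WT and 18.2% and 17.7% in MD1. When reads were pooled over genes, the share was 0.727% ± 0.0443 (SD, n = 2) in WT and 30.03% ± 1.36 (SD, n = 2) in MD1, since abundant genes weigh more in this measure. The median gene had a share of 0% in WT and 12.8% in MD1, and 173 genes had no JF1 read in either WT library. The difference in means exceeded the spread within each group many times over. The exact two-sided permutation test gave p = 0.333, the smallest that 2 libraries against 2 allow.

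**Figure D1:**
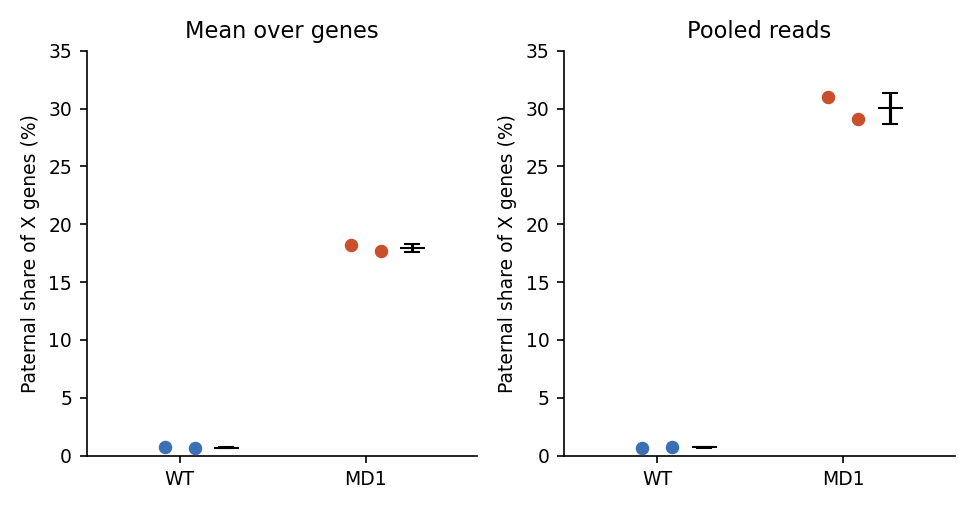
Paternal share of X-linked genes (%) in each library (points), with the group mean and SD of 2 libraries (bars), as the mean over 391 genes on the left and as pooled reads on the right. The MD1 libraries lie at 18.2% and 17.7% on the left, and the WT libraries at 0.723% and 0.659%.

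Most X-linked genes gained paternal reads in MD1. With edgeR, 291 of the 391 genes rose, 1 fell and 99 did not pass. The median rise of the 291 genes was 23.4 points, and in 287 of them both MD1 libraries lay above both WT libraries. Groups were apart in either direction for 78.3% of genes, against 33.3% by chance. Of the 291 genes, 258 were also called with each of the 4 libraries left out in turn, in fits that take the spread from the other genotype and assume that the lone library varies alike. Calls were more frequent at 328 genes with a mean of 100 or more reads (82.0% rose) than at the 63 shallower ones (34.9%), so a missing call at a shallow gene does not show that its share stayed the same.

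Several of the largest rises lay between 71468800 and 71699117 on X. Flna (X, 71468800 to 71491873), which encodes the actin crosslinker filamin A, went from 0.0775% ± 0.0155 to 49.2% ± 0.253 (SD, n = 2). Nearby, Atp6ap1, a subunit of the vacuolar proton pump, and Ikbkg, the regulatory subunit of the IKK complex, reached 51.6% ± 0.502 and 49.8% ± 0.247 (SD, n = 2) from at most 0.153% in WT. Dnase1l1, Fam50a and Lage3 from the same region reached 56.7% ± 4.36, 50.8% ± 0.0636 and 49.4% ± 1.57 (SD, n = 2). Outside it, Tlr13, a receptor for bacterial RNA, reached 56.8% ± 2.68 (SD, n = 2) from 0 of 116 WT reads, which allows a share of up to 2.59%. Haus7 reached 54.0% ± 5.35, Usp11 52.3% ± 3.72, Rbm10 48.7% ± 0.436 and Slc25a53 55.2% ± 9.58 (SD, n = 2), the last from 2.94% ± 4.16 in WT. The adjusted p of these genes in edgeR ranged from 4.38e-148 for Flna to 4.94e-09 for Slc25a53.

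Some deeply covered genes stayed close to silent on the paternal X. In 139 genes the share was under 5% in all 4 libraries, and in 76 it was under 1% in both MD1 libraries. Pls3, an actin-bundling protein gene with 14175 MD1 reads, had 0.0796% ± 0.0135 in WT and 2.73% ± 0.128 in MD1 (SD, n = 2). Col4a5, a basement membrane collagen gene, had 1.09% ± 0.479 in MD1, Amot 1.84% ± 1.08, Ids 4.18% ± 0.373, Tceal8 3.89% ± 0.475 and Armcx2 0.340% ± 0.0802 (SD, n = 2). All 6 nevertheless rose from WT values of at most 0.325%, with an adjusted p of at most 0.000517 in edgeR.

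The single fall was at Stard8 (X, 96237920 to 96270067), from 4 of 324 reads in WT (1.24% ± 0.0973, SD, n = 2) to 0 of 560 in MD1, which allows up to 0.536%. Its adjusted p in edgeR was 0.0264, and with any 1 of the 4 libraries left out it was 0.0529 to 0.244. Tro (2.45% in WT and 1.83% in MD1, adjusted p = 0.684 in edgeR) also had both MD1 libraries below both WT libraries without passing.

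With paternal expression called at a share of 10% or more, 8 genes qualified in WT and 213 in MD1 (54.5%). From WT to MD1, 205 genes crossed the bound upwards and 0 downwards. At a bound of 20% the WT count was 4. In MD1 50 genes had a share of 40% or more in both libraries, and 6 were above 50% in both.

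Of the 8 genes with a share of 10% or more in WT, 6 were on the list of genes known to escape X inactivation. Of 13 measured genes of that list, 7 had a share under 10% in WT and 6 a share of 10% or more. In edgeR 9 of the 13 rose and 4 did not pass, with 9 rising when adjusted over the list alone. Over all 391 informative genes 74.4% rose, so rises were not more frequent in the list. Of the 6 genes at 10% or more in WT, Ddx3x, Kdm5c and Pbdc1 rose. Ddx3x (X, 12858148 to 12871109), an RNA helicase gene, rose from 24.7% ± 0.444 to 43.3% ± 1.35 (adjusted p = 1.99e-08, edgeR), and the histone demethylase gene Kdm5c (X, 148667770 to 148713642) from 30.3% ± 0.223 to 39.4% ± 3.37 (SD, n = 2; adjusted p = 0.00119, edgeR). Its relative Kdm6a had 31.4% ± 1.79 and 40.9% ± 1.47 (SD, n = 2) without passing (adjusted p = 0.0655, edgeR). The noncoding gene 5530601H04Rik had 37.7% ± 5.54 and 38.8% ± 5.21, Ftx 19.99% ± 0.905 and 29.0% ± 0.594, and Firre 0.107% ± 0.151 and 0.135% ± 0.191 (SD, n = 2), none of which passed.

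The 3 largest gains in the list were at genes close to silent in WT. Utp14a rose from 1.52% ± 0.818 to 42.4% ± 0.548, 1810030O07Rik from 0.887% ± 0.279 to 41.8% ± 2.53 and Shroom4 from 0.0464% ± 0.0656 to 25.7% ± 1.76 (SD, n = 2). Bgn, the gene of the proteoglycan biglycan, rose from 0.0389% ± 0.000400 to 18.5% ± 4.61 (SD, n = 2). Mid1 rose from 3.11% ± 0.244 to 8.02% ± 1.62, Pbdc1 from 12.6% ± 0.0410 to 21.9% ± 2.197 and Car5b from 0.222% ± 0.314 to 3.48% ± 2.59 (SD, n = 2). The call for Pbdc1 (adjusted p = 0.0319, edgeR) was lost with any 1 library left out, at 0.0743 to 0.2002, and that for Car5b without MD1 replicate 2, at 0.162. Outside the list, and chosen after their values were seen, Tmsb4x, the gene of the actin-binding peptide thymosin beta 4, rose from 14.4% ± 0.00184 to 23.7% ± 1.47 (adjusted p = 5.13e-05, edgeR) and Tmem29 had 16.0% ± 0.0957 and 22.6% ± 0.755 (SD, n = 2; adjusted p = 0.0536, edgeR).

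**Figure D2:**
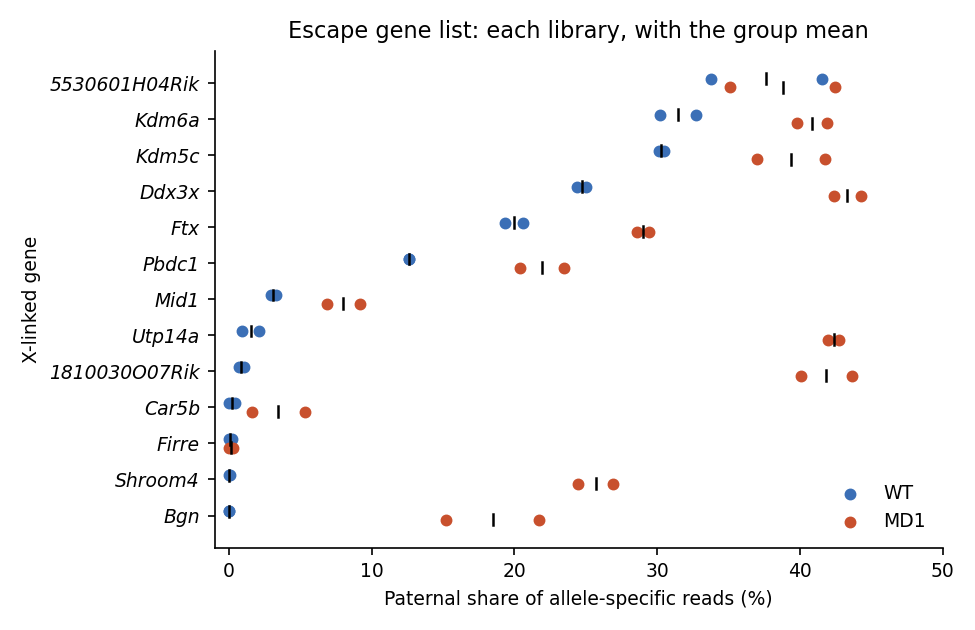
Paternal share of allele-specific reads (%) for the 13 measured genes of the escape list, with each of the 2 libraries per group as a point and the group mean as a vertical line. Utp14a goes from 1.52% in WT to 42.4% in MD1, while 5530601H04Rik lies at 37.7% and 38.8%.

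Genes with high paternal shares in MD1 lay next to each other along X. A run of 18 consecutive informative genes from Hcfc1 to G6pdx (X, 71188131 to 71699117, mm9) had shares of 31.4% to 56.7%, with a median of 47.5%. Runs of 12 genes from Otud5 to Ftsj1 (7418957 to 7829532) and of 10 genes from Snx12 to Ercc6l (98293125 to 99352430) had medians of 40.7% and 40.8%. Runs under 10% covered 9 genes from Gpr173 to Sat1 (148779189 to 151650992, median 1.14%) and 8 genes from Rab39b to Dmd (72817384 to 82450389, median 1.66%). Another such run of 8 genes, from Dach2 to Sytl4 (110411119 to 130516351), had a median of 3.88%. By bins of 10 Mb, the median rise was 33.3 points among 35 genes at 0 to 10 Mb and 30.2 points among 47 genes at 70 to 80 Mb. It was 0.465 points among 14 genes at 60 to 70 Mb and 2.08 points among 57 genes at 130 to 140 Mb. Neighbouring genes differed in rise by 12.7 points on average, against 18.7 in random orders (one-sided permutation p = 1e-05, the smallest that 100000 orders can give). Genes are not independent replicates, so the test describes these libraries.

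**Figure D3:**
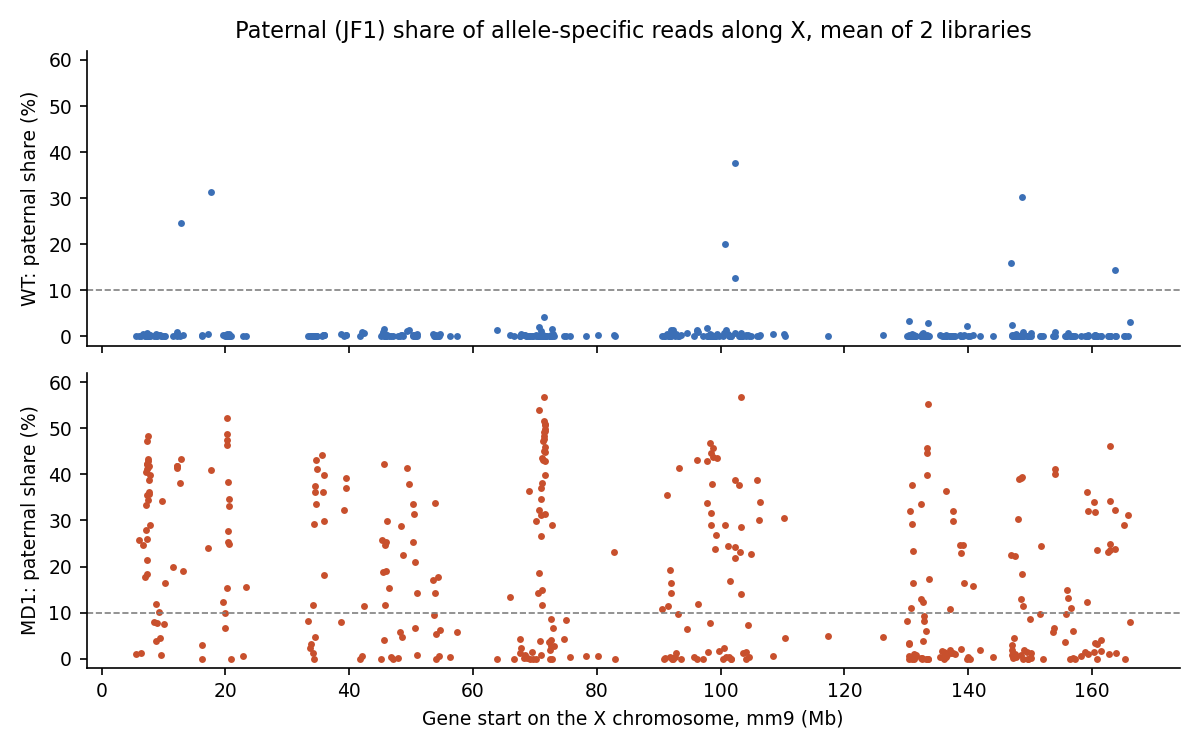
Mean paternal share (%) of each of 391 informative genes against its start on X (Mb, mm9), for WT above and MD1 below, with a dashed line at 10%. In WT 8 genes lie above the line, and in MD1 213 do, with a dense column of genes near 71.5 Mb.

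Total RNA of X-linked genes was higher in MD1 as a group. Among 398 X-linked genes the median log2 ratio of MD1 over WT was 0.22, and among 11001 autosomal genes it was 0.0012, a difference of 0.22. The X-linked median lay at percentile 100 of random lists, whose middle 95% spanned -0.038 to 0.031. The ratio was above 0 for 67.6% of X-linked and 50.2% of autosomal genes, and 19 X-linked genes were at least 2-fold higher and 9 at least 2-fold lower. Without a filter on FPKM the difference was 0.052, since many genes near 0 enter.

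Over 11399 genes, 158 were at least 2-fold higher in MD1 and 320 at least 2-fold lower. With a pseudocount of 0.1 the counts were 259 and 494, and with a filter at a mean FPKM of 5 they were 94 and 191. These ratios compare group means without replicates, so a single library could drive a ratio. The F1 fathers pass on autosomal JF1 alleles only in inherited blocks, so the groups may also differ in these alleles. For autosomal genes, here and in the gene lists, this cannot be told apart from the MD1 genotype. Other differences between the cultures, in these ratios and in the gene lists, cannot be told apart from the genotype either. The highest ratios included the acute-phase gene Saa3 (0.816 to 150.2 FPKM, log2 ratio 6.38), the neutrophil-attracting chemokine genes Cxcl5 (1.33 to 152.1, 6.04), Cxcl1 (0.554 to 26.9, 4.17) and Cxcl3 (0.307 to 21.9, 4.13), and the prolactin family genes Prl2c3 (0.138 to 48.7, 5.45) and Prl2c2 (0.768 to 33.9, 4.30). The overlapping genes Klra18 and Klra4, whose reads may be shared, had 3.59 and 3.47, and Crct1 had 3.43. The lowest included Eln, which encodes elastin (70.8 to 1.26 FPKM, -4.99), the small proteoglycan gene Aspn (29.9 to 0.871, -4.05), the bone sialoprotein gene Ibsp (14.7 to 0.0172, -3.95), Gstp2 (40.3 to 0.195, -5.11) and Gm1821 (31.5 to 0.709, -4.25). Ribosomal protein genes made up 3 of the 12 highest (Rpl10, Rpl24 and Rpl36a at 6.57, 6.18 and 3.92) and 7 of the 12 lowest (Rps12, Rpl23a, Rpl11, Rpl10a, Rpl27, Rpl12 and Rps13 at -6.83 to -4.13). Such genes have near-identical copies in the genome, so their FPKM is uncertain. Whether Prl2c3, Prl2c2, Gstp2 and Gm1821 have such copies was not checked, so their ratios may be uncertain too. Thbs1 had 1012 FPKM in WT and was listed at 0 in MD1. A listed 0 can be a failed estimate and does not show a loss of its RNA, so no ratio was formed.

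Muscle and matrix genes were lower in MD1. All 10 measured skeletal muscle genes had lower values, with a median log2 ratio of -1.50 (percentile 0), including Actc1 (22.8 to 4.96 FPKM), Des (46.2 to 11.99), Acta1 (67.1 to 21.3) and Myh3 (5.51 to 1.16). Among 12 smooth muscle genes, 1 of which (Des) is in both lists, the median was -0.91 (percentile 0), with Myh11 at 25.6 and 2.31, Actg2 at 355.3 and 122.1 and Mylk at 6.27 and 1.91 FPKM. The median of 11 cartilage and bone genes was -0.66 (percentile 0.02), with Col11a1 at 122.7 and 36.6 and Comp at 2.35 and 0.264, while Sox9 was higher at 4.41 and 7.10. With a pseudocount of 0.1 this median was -1.15. Of 37 extracellular matrix genes 30 were lower (median -0.50, percentile 0), among them Ogn (77.4 to 6.04), Fbln5 (133.8 to 23.5) and Efemp1 (368.2 to 78.8), and Col6a3 was higher (13.2 to 49.0). The 18 fibroblast genes had a median of -0.074 (percentile 15.7), with Fn1 higher (370.2 to 940.4) and Col3a1 lower (188.9 to 78.7).

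Cell-cycle and interferon genes were higher. All 26 proliferation genes had higher values in MD1 (median 0.71, percentile 100), among them Mki67 (15.8 to 32.8 FPKM), Pcna (42.7 to 83.3), Cdk1 (32.0 to 61.3) and Mcm6 (33.7 to 63.1). Of 20 p53 and senescence genes 19 were lower (median -0.63, percentile 0), including Gdf15 (18.1 to 5.62), Btg2 (44.6 to 18.5), Cdkn2b (89.1 to 38.3) and Perp (54.3 to 26.8). Of 17 interferon-response genes 14 were higher (median 0.90, percentile 100), with Ccl5 at 0.424 and 7.39, Bst2 at 13.4 and 62.7, Isg15 at 1.86 and 11.3 and Ifi27 at 4.05 and 14.4 FPKM. The interferon median was 1.44 with a pseudocount of 0.1 and 0.53 without a filter on FPKM. The 26 silencing factors, Smchd1 among them, had a median of 0.22 (percentile 99.8), with Dnmt1 at 25.7 and 43.4 and Ezh2 at 20.1 and 33.0. The 14 stress genes had a median of -0.30 (percentile 0.17), with Fos at 21.7 and 7.84 and Dusp1 at 71.7 and 42.7.

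Imprinted genes outside the Snrpn and Igf2r regions were mostly lower, 34 of 41 (median -0.31, percentile 0). Mest had 65.4 FPKM in WT and 5.78 in MD1, the noncoding RNA gene H19 992.1 and 132.6, and Dlx5 6.47 and 1.58, while Tfpi2 had 3.39 and 18.8. Near Snrpn and Igf2r 4 genes passed the FPKM filter, too few for a median, with Peg12 at 5.05 and 16.4, Ndn at 63.9 and 128.1, Airn at 1.32 and 3.08 and Igf2r at 104.2 and 65.4 FPKM. Without the filter 8 genes of this list had a median of 0.35 (percentile 99.97), 6 of them above 0. The 25 clustered protocadherin genes had a median of -0.28 (percentile 0.42) and went both ways, with Pcdha10 at 0.207 and 2.81, Pcdha9 at 0.103 and 1.94, Pcdhga8 at 2.24 and 0.713 and Pcdhgc5 at 5.85 and 2.75. Without a filter on FPKM the direction was reversed, with a median of 0.025 over 55 genes (percentile 98.9), 31 of them above 0. Many of these cadherins share exons, so the values of those genes are uncertain. The 33 Hox genes had a median of -0.010 (percentile 49.8; 0.013 with quantile normalization), with Hoxd12 at 3.67 and 1.13 and Hoxc10 at 10.4 and 19.8.

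The total RNA of 14 escape list genes had a median of 0.12 (percentile 88.8), with Utp14a at 17.1 and 36.8 FPKM and Firre at 2.998 and 1.64. The 12 blood and immune genes had a median of -0.25 (percentile 2.78), with C1qb at 7.20 and 3.59, the 7 neural genes -0.12 (percentile 19.5; mean 0.047, of opposite sign), with Stmn2 at 9.62 and 24.8 and Map2 at 6.44 and 2.05, and the 5 epithelial genes -0.012 (percentile 51.8; 0.060 with quantile normalization), with Krt18 at 17.1 and 22.1. The 4 endothelial genes measured were Flt1 at 4.32 and 9.59, Emcn at 4.12 and 1.58, Egfl7 at 2.44 and 3.08 and Kdr at 3.26 and 3.02 FPKM. The 1 erythroid gene was Hbb-bh1 at 1.6 and 1.27. No X-linked gene of the germline families passed the FPKM filter. The 4 genes that passed, Tcfl5, Slx1b, Slx4ip and Slx4 (log2 ratios of 0.81, -0.46, -0.19 and 0.074), are autosomal and entered by their symbols, so the list gave no result for X-linked families.

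**Figure D4:**
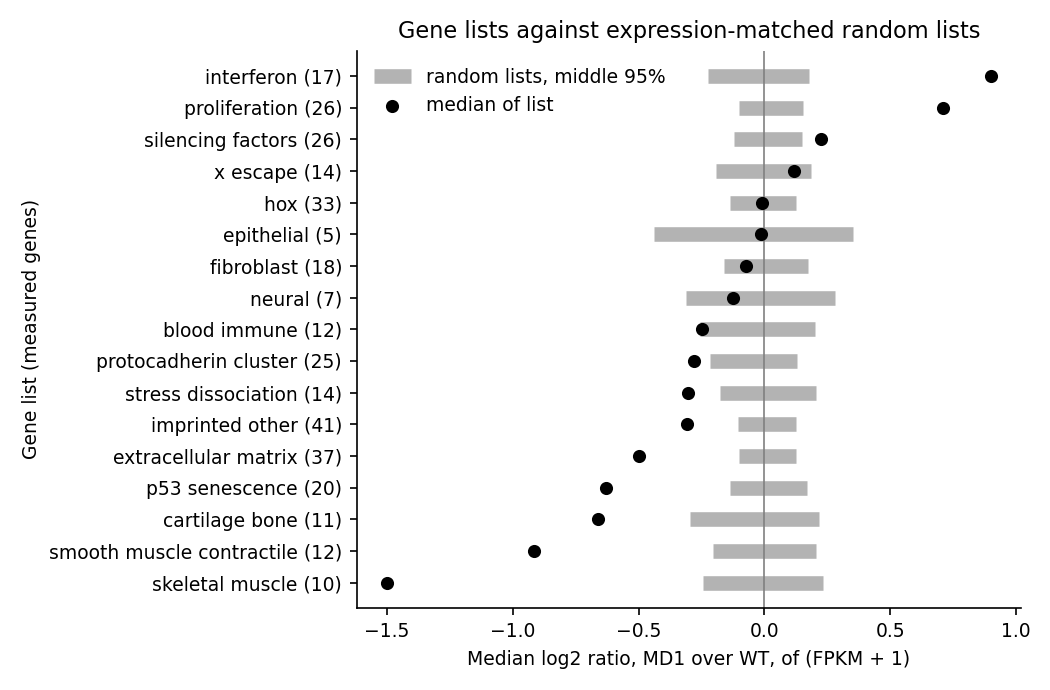
Median log2 ratio, MD1 over WT, of (FPKM + 1) for each gene list (points), with the number of measured genes in brackets and the middle 95% of 10000 expression-matched random lists as grey bars. Skeletal muscle lies lowest at -1.50 and interferon genes highest at 0.90.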

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

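All tests in this part were chosen after the result was seen, except that on residuals, which was planned after the stretches along X were seen but before its own value was.

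Among X genes outside the comparison, whose reads or shares missed its minimum, 12 had over 3 paternal reads in MD1 and a Wilson 95% lower limit of the MD1 share above the upper limit in WT or, where no pooled WT share was given, above 10%. All 44 MD1 reads of Trap1a were paternal (100%, Wilson 95% lower limit 92.0%), while its FPKM went from 0.0256 to 6.34, and WT had 2 reads. Tktl1 had 81.2% of 101 reads against 0 of 19 in WT, which allows up to 15.8%. Araf had 75.3% of 73 reads, with 7 reads in WT. The FPKM of Araf went only from 28.7 to 41.6, so its reads did not follow its FPKM. The paternal share in MD1 was 56.5% at Was, 46.9% at Btk, 41.2% at Ribc1, 36.8% at Jpx, 31.7% at Nlgn3, 30% at Itgb1bp2, 27.8% at Porcn, 25.8% at Gm6377 and 22.7% at Pcsk1n. With MD1 replicate 1 left out, the share was 46.4% of 28 reads at Nlgn3 and 50% of 8 at Itgb1bp2. With MD1 replicate 2 left out, it was 0 of 13 at Nlgn3, which allows up to 23.1%. It was then 16.7% of 12 at Itgb1bp2 and 40% of 5 at Pcsk1n. These 3 shares moved with the library left out. At Itgb1bp2 and Pcsk1n, so few reads cannot tell a difference between libraries from counting error. No pooled WT share was given for Trap1a, Tktl1, Araf, Btk, Ribc1 and Pcsk1n.

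The paternal share rose at some X genes and stayed near 0 at others, in stretches. A mix with fibroblasts whose JF1 X was active would lift all expressed genes, but 116 informative genes had a 95% upper limit of the MD1 share under 5%. Reads shared by adjacent genes are argued against by neighbours at least 100 kb apart, which still differed by only 12.8 points (18.7 in random orders). After linear regression on ranked FPKM and reads, all neighbours differed by 12.6 points against 17.4 in random orders (permutation p = 1e-05, the smallest possible). A linear effect of these ranks therefore does not account for the stretches. Other forms of dependence on level or depth stay in the residuals and were not tested. A loss of silencing by region in the MD1 genotype may underlie them, which stays a hypothesis and was not tested apart from the group difference.

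Ribosomal protein genes were over-represented among extreme FPKM ratios, with 14 of 83 at least 4-fold apart (16.9%, against 0.627% of other genes), 11 of them lower and 3 higher in MD1. A shared change would move them together, but their median log2 ratio was 0.058, with quartiles of -0.16 and 0.18. FPKM moved between a gene and its near-identical copies could give ratios both ways. For Rpl10 the FPKM ratio was 171 while allele-specific reads went from 24 to 139, so the FPKM fold was 29.5 times that of the reads. With 1 such gene this cannot be told apart from other causes, and no biological explanation was tested.

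Genes with larger rises in paternal share had higher ratios of total RNA. A scaling of all genes is argued against by the autosomal median log2 ratio of 0.0012. Over 344 genes the observed log2 ratio followed the one computed from the paternal shares with a slope of 1.12 (95% bootstrap interval 0.965 to 1.27), so a fall in B6 output that held totals constant, which needs a slope near 0, is argued against by the lower limit of 0.965, and paternal output may add to B6 output. B6 output itself was lower than that of matched autosomal genes (median -0.088, random lists -0.040 to 0.042), and it was lower also at 94 genes whose share rose by under 2 points (-0.15), for a cause that was not tested. Genes are not independent replicates, and both ratios come from the same libraries.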

How the results depend on the processing

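The alternatives that left out genes whose reads and FPKM disagree, thinned reads, set neighbours at least 100 kb apart or left out ribosomal protein genes were chosen after seeing the data. The difference in mean paternal share of 17.2 points became 29.3 with pooled reads, 12.8 as a median and 18.7 with a read minimum 5 times higher, because these weigh genes differently. It was 17.0 to 17.5 with 1 library left out. The count of genes higher in MD1 stayed within 260 (thinned reads) to 293 (Fisher's exact test), against 291, and was 270 to 280 with 1 library left out. Each such fit has 1 library in a group, takes the spread from the other genotype and assumes that the lone library varies alike, so it is a weak check of stability. The 1 gene lower in MD1 became 2 with limma on the share and 0 with thinned reads, and was 0 with any library left out, while with all libraries 1 gene (Stard8) was lower at an unadjusted p under 0.05 in edgeR. Genes with paternal expression in WT numbered 4 at a bound of 20%. Genes at least 2-fold higher in total RNA numbered 259 with a pseudocount of 0.1 and 94 with a filter at a mean FPKM of 5, and lower ones 494 and 191, since fewer genes enter under the filter. The protocadherin median was reversed to 0.025 (percentile 98.9) without a filter, and the cause was not tested. Blood and immune genes passed the percentile bound with a pseudocount of 0.1 (-0.35) and without a filter (-0.22), and neural genes without one (-0.14), while all 17 lists with a median stayed on their side of the bound with quantile normalization, with median-ratio scaling and without ribosomal protein genes. The interferon median of 0.90 was 1.44 with a pseudocount of 0.1 and 0.53 without a filter, that of cartilage and bone genes was -1.15 with a pseudocount of 0.1 against -0.66, and the Snrpn and Igf2r list, without a median under the filter, had 0.35 (percentile 99.97) over 8 genes without it. The X to autosome difference was 0.052 without a filter and 0.22 to 0.26 in the other settings. The replicate numbers do not pair the samples by any label, and with 2 pairs the correlation of deviations was 0.0847 for shares and 0.395 for reads. With the replicate block the difference in share was 17.2, 284 genes were higher and 0 lower, and 281 of the 291 genes were called in both fits. Of the 13 escape genes, Kdm5c (adjusted p = 0.111, edgeR) and Pbdc1 (0.0646) were not called with the block, while Kdm6a was (0.0389). Not run, because FPKM is given as 1 mean per group, were the tests of total expression and lists with other tools, with a block, with an estimated correlation or with a library left out. Fewer genes were called among those with under 100 reads (34.9% of 63) than among deeper ones (82.0% of 328), and at the read numbers of all 391 genes a simulated rise of 2 points was called in 47.2%.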

Other observations

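The tests of gene length and expression level were planned before their values were seen, and the tests of chemokine genes, distance from Xist and paternal excess were chosen after.

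Of 20 measured Cxcl, Ccl, Ppbp and Pf4 genes, 12 were at least 2-fold higher in MD1 and 1 at least 2-fold lower. The list was made after 9 of them were seen among the 30 largest ratios. The other 11 genes had a median log2 ratio of 0.57, at percentile 100 of matched random lists (-0.29 to 0.22), with 7 above 0, 3 at least 2-fold higher and 1 at least 2-fold lower. Ccl2, which attracts monocytes, went from 31.4 to 309.7 FPKM, Ccl7 from 45.0 to 172.0 and Ppbp from 8.54 to 52.2, while Cxcl14 went from 19.3 to 7.18 and Cxcl12 from 309.2 to 228.8. The cytokine gene Il6 went from 1.40 to 18.6 FPKM. Ccl5 and Cxcl10 are also in the interferon list.

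Allele-specific reads of a few genes did not follow FPKM. Plp2 had 1225 reads in WT replicate 1 and 0 in the other libraries, with 84.2 FPKM in WT and 173.2 in MD1. Cox7b had 2047 reads in MD1 replicate 1 and 26 in MD1 replicate 2, Morf4l2 had 90 and 6243, and Apoo had 185 and 252 reads in WT and 0 in both MD1 libraries. Sat1 had 788 and 1079 reads in WT and 30 and 87 in MD1, at 155.7 and 145.5 FPKM.

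The size of the rise in paternal share was set against 3 gene properties across 391 genes, which are not independent replicates. Neighbouring genes had similar rises, and the permutations of single genes ignore this, so the p-values may be far too small. It was larger at genes with higher WT expression (Spearman 0.371, permutation p = 1e-05, the smallest possible, adjusted 3e-05; Pearson on log10 values 0.283, p = 1e-05, and 0.297 without the 2 farthest genes). Among the more highly expressed genes, split at the median, the Spearman value was 0.0823, so expression may matter mainly among low genes, where depth is also lower. Shorter genes rose more (Spearman -0.210, permutation p = 4e-05, adjusted 6e-05; Pearson -0.198, p = 9e-05, and -0.190 without the 2 farthest), with -0.0740 among highly expressed genes and -0.227 among the others. Distance from Xist gave a Spearman value of 0.153 (permutation p = 0.0026, adjusted 0.0026) and a Pearson value of 0.0717 (p = 0.16; 0.0579 without the 2 farthest), so it is a weak candidate.

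With the reads of both MD1 libraries pooled, the paternal share had a Wilson 95% lower limit above 50% at 7 genes (Araf, Haus7, Tktl1, Dnase1l1, Atp6ap1, Tlr13 and Trap1a). The limit leaves out the spread between libraries and was not adjusted over genes. Haus7 had 57.8% in MD1 replicate 1 and 50.2% in MD1 replicate 2, and Atp6ap1 had 51.2% and 51.9%. Little B6 expression could give such an excess, as at Trap1a (0.0256 FPKM in WT). Tktl1, Tlr13 and Dnase1l1 had 0.0739, 0.753 and 4.22 FPKM in WT, but Haus7, Araf and Atp6ap1 had 18.8, 28.7 and 191.1. The reads of Araf did not follow its FPKM. The median WT FPKM of the 7 genes was 4.22 against 5.65 at 431 other genes (two-sided permutation p = 0.65), so with 7 genes the test leaves this open.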
